A study of Bos taurus with 30 samples.

How the data were processed

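Testes RNA from 30 Holstein-Friesian bull calves was profiled by RNA sequencing, with 1 library per calf. Per the labels' protocols, RNA was purified with a column kit that removes genomic DNA, and libraries were made with a strand-preserving Illumina kit from polyadenylated RNA. The submitters' processing notes name FastQC 0.11.8, cutadapt 2.6, STAR 2.6.1, R 3.4 and edgeR 3.5, and the cattle genome build UMD3.1. The gene annotation, the counting program and its strand setting are not given in the sources used here.

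The deposited expression table had 30 library columns and 27607 gene rows, all with Ensembl cattle gene identifiers. Although the authors' table is titled as counts, 24269 of the gene rows held at least 1 value that was not a whole number, so the deposited values were not raw counts. All 598503 values above 0 were, within a tolerance of 0.001, whole multiples of the smallest value of their column, as reads divided by 1 constant per library would be. Reads per gene could therefore be recovered for a count-based test, which was not done here.

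Each calf carries the plane of nutrition in 2 places, a free description and a diet label. Calves were grouped by both before the data were examined. The calves with matching labels formed a High group and a Moderate group, and the calves with opposing labels were kept as 2 further groups. The planned primary comparison was between the calves with matching labels. Comparisons of all 30 calves, 15 against 15, were also planned by the description alone and by the diet label alone. A further planned comparison was between the 2 groups with opposing labels.

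The planned comparisons were not computed. None of the 30 column names occurred in the labels of a calf, and none of the numbers in the column names was the title of a calf. The names end in H for 15 columns and in L for 15 columns, with no key to these letters in the sources used here. A split of 15 against 15 has the group sizes of the description alone and of the diet label alone, but not those of the grouping fixed on both labels, whose largest group held 9 calves. Columns were used only where a name matched 1 calf or 1 of the fixed groups with room for them. By this choice all 30 columns were left out of any comparison, and the H and L columns were not compared. Their values served only to check the unit of the table, and no expression level, depth or fold change is given.

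The gene identifiers were compared with a reference table of 37063 cattle genes from NCBI. None of those genes carried an Ensembl identifier in that table, and 0 of the 27607 identifiers were matched to a symbol. The 26 gene lists and 18 single genes chosen before the data were examined were not tested. No symbol was matched, and no column entered a comparison.

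The computations covered how often both labels named the same plane and whether the table could be joined to calves and symbols. They also covered whether the table's values were whole numbers or whole multiples of the smallest value of their column. All were run in Python 3.11.15. The labels were counted over the whole series, so no interval or test was attached to that count. The 77 alternative settings listed before the data were examined all concerned the expression comparisons and were not run. A match of column numbers to calf titles and a stricter tolerance for whole multiples were added after the data had been seen.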

Results

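The series addressed how the plane of nutrition in early life affects gene expression in the testes of bull calves. Holstein-Friesian calves, a dairy breed, were fed a High or a Moderate plane from 2 to 12 weeks of age, and testes were sampled at 12 weeks. The High plane provided 1.5 kg of milk replacer in 10 litres per day with free access to concentrates, for a target gain of 1.0 kg per day. The Moderate plane provided 0.5 kg of milk replacer in 4 litres per day with 0.5 kg of concentrates, for a target gain of 0.5 kg per day. The stated design had 15 calves on each plane, 30 in all.

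The description and the diet label named opposite planes for most calves. Each label taken alone placed 15 calves on the High plane and 15 on the Moderate plane. Both labels named the High plane for 6 calves, and both named the Moderate plane for 6 calves. A further 9 calves were described as High and carried the diet label Moderate. The remaining 9 calves were described as Moderate and carried the diet label High.

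The labels thus matched for 12 of the 30 calves, or 40.0%, and opposed each other for 18. Unrelated labels that each split the calves equally would on average match as often as they oppose each other. The match here was no closer than that. The labels alone do not show which of them is right, and a match does not establish the plane of the 12 calves.

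The comparison of testes expression between the High and Moderate planes was not analysed here. The 30 library columns of the expression table, 15 with names ending in H and 15 with names ending in L, were not joined to calves or to the groups formed from both labels. The H and L columns have the group sizes of either label alone, and leaving out their comparison was a choice. No gene is therefore reported as higher, lower or not differing between the planes. No statement is made on any cell type or pathway of the testis.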

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

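The 77 alternatives planned before the data were examined all concerned the expression comparisons and were not run, because the 30 library columns were not joined to calves or to the groups fixed on both labels. They covered the normalization, the filter on low counts, the test, the threshold, a surrogate variable, the choice of label and the calves left out in turn. One of them would have grouped the libraries by a plane named in the column names. That setting had been listed in advance and its group sizes of 15 and 15 fit either label alone, so leaving it out was a choice. It was left out because columns were used only where they matched a calf or a fixed group. No expression result exists whose stability could be judged. Alternatives chosen after the data had been seen concerned the join and the unit of the table. Matching the number in the column name to the whole title of a calf gave 0 columns. A search of the labels for the whole column name also gave 0. The number was not sought within longer titles or in the other labels. With a tolerance of 1e-06 in place of 0.001, all 598503 values above 0 were still whole multiples of the smallest value of their column. Depth sets no limit on the share of calves whose labels agree.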
